A study of Homo sapiens with 12 samples.

How the data were processed

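The samples are 12 droplet single-cell RNA libraries of human G-CSF-mobilised blood progenitors sorted as CD34+CD38-CD45RA-, per the labels. Cells carried a non-targeting (control) or a RUNX1-targeting lentiviral shRNA and were sorted into CD41- and CD41+ fractions, with replicates 1 to 3 in each of the 4 groups. The text of the series record describes another cell source and another surface marker, and the sample labels were followed. The labels do not say whether libraries share a donor or what the replicate number marks.

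Per the file headers, the deposited matrices hold counts (raw unique molecular identifiers, UMIs, per gene and barcode) that the authors made with Cell Ranger 4.0.0. The deposited barcode and feature files hold identifiers, a unit of other kind. GRCh38 is the genome the submitters name; the annotation release and the rule that kept barcodes as cells are not given in the sources used here. The features are 36601 in every library. The deposited tables of the authors hold natural log (ln) fold changes with an adjusted p_value per cluster or gate, and in another table a ratio of RUNX1 shRNA over control with an adjusted p_value per named population. The deposited adjusted p-values (a step-up FDR in the table of populations) were computed by the authors. That the fold changes are natural logs follows from their values. The authors' test, the pooling of replicates and the assignment of cells to clusters are not given in the sources used here, so these tables served only for a comparison of signs with no test.

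Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, 91309 of 92635. A stricter filter asked for 1000 genes and at most 10%. Doublets were kept, because the automatic threshold of the doublet score called 0 to 6 barcodes per library. An alternative left out the highest scores at 0.8% per 1000 barcodes. Totals ran from 1.40 to 40.7 mega-UMIs (M) per library. UMIs were summed over the kept cells of each library, and 15726 genes passed the count filter of edgeR. XIST, TSIX and Y-linked genes were left out of all tests and tables.

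The 5 comparisons are RUNX1 shRNA over control in CD41- and in CD41+ libraries, CD41+ over CD41- in control and in RUNX1 shRNA libraries, and the difference of the shRNA effects between the gates. Fold changes come from edgeR 4.0.16 (quasi-likelihood fit, robust, TMM factors, 1 mean per group) with limma 3.58.1 under R 4.3.3. All tests are 2-sided. Adjusted p is by Benjamini-Hochberg over genes with a threshold of 0.05. CPM is UMIs per mega-UMI on TMM-scaled library sizes unless said otherwise, and the ± after a CPM is the SD of 3 libraries. The ± after a log2 fold change is its SE. The p-values measure only the spread between these samples, which may be technical. DESeq2 1.42.0, RLE factors, no count filter, only the libraries compared, the other cell filters, libraries thinned to the smallest total, and omission of each library in turn were the alternatives fixed in advance.

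A fit with the replicate number as a block was planned as an alternative. Over 5854 genes the deviations from the group means correlated at 0.80 to 0.93 in all 18 pairs of libraries with the same number. Replicate 1 correlated with replicate 2 at 0.75 to 0.92 (12 pairs), and replicate 3 with either at -0.93 to -0.78 (24 pairs). The negative values follow in part from taking deviations from group means. The data thus set replicate 3 apart from replicates 1 and 2. With replicate 3 this far off, the deviations of replicates 1 and 2 both mirror it. The values can thus neither show nor exclude a pairing by number between replicates 1 and 2, and the labels give no source for one. Block values are given beside a result where they change a call or move a count by over 1.5 times. A fit of replicates 1 and 2 only, with the replicate 3 fold (no test), is also given.

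In simulated data all counts were drawn from the means and dispersions of the block fit, with 200 genes changed. Genes were drawn independently and replicate effects were equal in all groups, so the block model held by construction. The recovery rates therefore favour the block fit, and none of the rates need hold for the real counts. The fit without block found 1.94% to 11.2% of genes with a log2 change of 1. It found 53.6% to 69.3% of those with a log2 change of 2, with at most 1 false call. The block fit found 98.0% to 99.0% and 99.0% to 100.0%, with false calls above the nominal 5% of its calls in all 4 comparisons (23 of 222, 18 of 215, 11 of 210 and 12 of 210). A gene that does not pass without block may thus still differ.

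Gene lists, 35 in number and written from general knowledge, were tested with camera (correlation 0.01), which compares a list with all other genes. Beside it stand camera with an estimated correlation and fry. Fry asks whether a list moves on balance in 1 direction and compares it with no other genes. Counts of list members use the adjustment over all genes; "over the list alone" gives the count when adjusted among the members. A gene with 0 UMIs in all libraries of a group gets no fold in the text, and a second median sets such members at a bound of 3 counts.

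Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2: counts scaled to 10000, log, 2000 variable genes, 30 principal components, 7 neighbours per replicate number, resolution 0.8 (1.6 and 0.4 as alternatives), seed 1. Genes with unadjusted p under 0.05 for the shRNA in either gate in the fit with the block, 4650 in all, were left out of the clustering, so 1422 variable genes remained. The clusters number 13. A cluster got the name of a marker list when at least 3 of its top 20 genes belong to it, no other list has more of the top 10, and its cells do not come mostly from 1 library. The last condition leaves cluster 6 unnamed (82.8% of it is control CD41- replicate 3), although 3 of its top 20 are stem and multipotent progenitor markers. Shares were tested with edgeR on cells per class (library cell total as size) and with exact permutation of libraries, whose smallest possible p with 3 against 3 is 0.1. Genes within a class were fitted where a library had at least 30 cells, and are reported where all 3 libraries of both groups did. Cell cycle phases came from the scanpy score on counts thinned to 3000 UMIs (also 1500 and unthinned). A sign-flip over 3 pairs has 0.25 as its smallest possible p. Intervals on shares of 1 library are exact binomial 95% intervals and cover counting error only.

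The named genes follow a rule: adjusted p under 0.05, mean log2 CPM of at least 4 and no overlap of the 3 against 3 libraries, then the 8 largest positive and the 8 largest negative folds; up to 3 members of each list with the smallest p that pass; and always RUNX1, ITGA2B, GP1BA, GP9, CD34, CD38, PTPRC, MYH10, PF4 and TGFB1. HLA genes, immunoglobulin and T cell receptor segments, mitochondrial genes and clone names are kept out of the 8 and 8. For classes the 5 smallest adjusted p in each direction are named. The text prints a part of these.

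The comparisons, lists, filters, fits, naming rule and most alternatives were fixed before the data were examined. Chosen after the data were seen: leaving shRNA-responsive genes out of the clustering, the details of cluster naming, reporting class fits only with 3 against 3 libraries, the fit of replicates 1 and 2, leaving out both CD41- replicate 3 libraries, leaving out the barcodes of cluster 6, and clustering on all variable genes. Further software: python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9. Gene coordinates are GENCODE 29 on GRCh38.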

Results

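RUNX1 is a transcription factor of blood stem cells and of the megakaryocyte lineage, which makes platelets. The libraries hold human mobilised blood progenitors with a control shRNA or an shRNA against RUNX1, sorted by surface CD41, the integrin alpha-IIb that ITGA2B encodes and that marks cells with megakaryocyte priming. Each of the 4 groups (control or RUNX1 shRNA, CD41- or CD41+) has 3 libraries. Kept cells per library, in the order of replicates 1, 2 and 3, were 12951, 10807 and 5898 in control CD41-, 12600, 11178 and 814 in RUNX1 shRNA CD41-, 10772, 11533 and 1010 in control CD41+, and 5317, 4744 and 3685 in RUNX1 shRNA CD41+. Their totals were 36.0, 31.3 and 40.7, then 36.4, 35.2 and 1.40, then 32.2, 33.2 and 4.53, and 19.6, 21.9 and 16.2 mega-UMIs (M).

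The replicate 3 libraries differ from the others in kind as well as in depth. Their median mitochondrial share per cell was 1.45% to 3.31%, against 9.02% to 11% in replicates 1 and 2. MALAT1, a nuclear RNA, stood at 829 (control) and 1309 (RUNX1 shRNA) CPM without TMM scaling in the CD41- replicate 3 libraries and at 5878 to 6410 in the other CD41- libraries. Counts of replicates 1 and 2 of a group differed by a chi-square per degree of freedom of 1.97 to 8.61, and those of replicate 3 from either by 20.2 to 476. No library repeats another.

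How far did the RUNX1 transcript itself fall? RUNX1 (ENSG00000159216, chr21:34787801-36004667, minus strand) stood at 58.4 ± 23.2 CPM in RUNX1 shRNA CD41+ libraries and 109.5 ± 45.7 in control, a log2 fold change of -0.91 ± 0.51 that does not pass the test (adjusted p = 0.760). With the replicate number as a block it passes (-0.90, adjusted p = 7.32e-05; adjusted p over all alternatives 2.99e-22 to 1.0). Replicates 1 and 2 gave -0.93 and replicate 3 gave -0.83, so the level was lower under the shRNA at all 3 replicate numbers. The spread without block includes the lower level of replicate 3 in both arms. In control CD41+ libraries it was 56.9 CPM, against 138.1 and 133.6 in replicates 1 and 2. In CD41- cells the level was 49.0 ± 20.8 against 64.0 ± 30.6 CPM (-0.35 ± 0.51, adjusted p = 1.0; block -0.36, adjusted p = 0.864; adjusted p over all alternatives 1.01e-09 to 1.0), with -0.42 in replicates 1 and 2 and -0.19 in replicate 3. Without TMM scaling the replicate 3 order turns round, 23.5 under the shRNA against 18.1 CPM in control. RUNX1 transcript was present in every library.

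**Figure D1:**
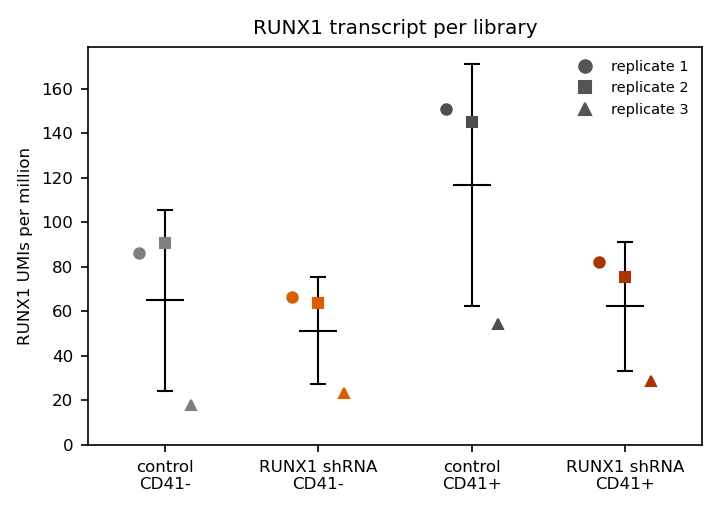
RUNX1 CPM without TMM scaling (vertical axis) in each of the 12 libraries by group (horizontal axis), with a marker shape per replicate number. Black marks with lines are group means with SD. CD41+ control libraries lie at 151, 145 and 54.3 and CD41+ RUNX1 shRNA libraries at 82.4, 75.6 and 28.8, each lower at the same number.

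What differs under the RUNX1 shRNA in CD41+ cells? Of 15726 genes, 117 rose and 10 fell, and 1342 had an unadjusted p under 0.05. The largest rise among well expressed genes was that of KLF6 (ENSG00000067082, chr10:3775996-3785281, minus), an immediate early zinc finger factor, from 22.6 ± 5.92 to 137.3 ± 56.0 CPM (log2 fold change 2.59 ± 0.46, adjusted p = 0.0295). LXN (ENSG00000079257, chr3:158645822-158672693, minus), a carboxypeptidase inhibitor that limits stem cell numbers in mice, went from 45.4 ± 14.7 to 244.9 ± 13.4 CPM (2.44 ± 0.33, adjusted p = 0.00842). ADD3, a membrane skeleton protein, rose by 2.14 ± 0.40 (adjusted p = 0.0340), GBP4, an interferon-induced GTPase, by 1.81 ± 0.32 (0.0295), and TSC22D1, a leucine zipper factor induced by TGF-beta, by 1.79 ± 0.22 (0.00567; 50.1 to 173.1 CPM). SAMSN1, an adaptor of lymphoid and mast cells, rose by 1.77 ± 0.20 (0.00357), ATP1B1, a sodium pump subunit, by 1.5 ± 0.29 (0.0390) and FSCN1, an actin bundler, by 1.42 ± 0.27 (0.0390). The only well expressed gene among those that fell and are named is NSA2 (ENSG00000164346, chr5:74766991-74780113, plus), a factor of 60S ribosome assembly, from 169.8 ± 5.57 to 77.3 ± 11 CPM (-1.13 ± 0.22, adjusted p = 0.0406).

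Genes of the MHC class II, which present antigen and mark the less committed progenitors, make the clearest group: 5 of 12 rose (8 over the list alone), 0 fell, with a median log2 fold change of 1.31. HLA-DQA1 (ENSG00000196735, chr6:32628179-32647062, plus) rose by 2.08 ± 0.24 (adjusted p = 0.00357; 6.10 to 25.1 CPM), HLA-DQB1 by 1.67 ± 0.26 (0.0173) and HLA-DOA, at under 1 CPM, by 2.34 ± 0.43 (0.0314). Reads of HLA genes map by allele, and the labels do not say whether control and RUNX1 shRNA libraries share a donor. Interferon-induced IFIT2 (2.15 ± 0.34, adjusted p = 0.0173), IFIT3 (1.38 ± 0.25, 0.0296) and EPSTI1 (1.39 ± 0.20, 0.00919) rose, 3 of 41 in that list (7 over the list alone). So did genes of stem cells: CRHBP, a stem cell marker (2.58 ± 0.46, 0.0291), MLLT3, a factor of stem cell maintenance (1.17 ± 0.24, 0.0491), and ERG, a factor of stem and megakaryocyte cells (1.80 ± 0.27, 0.0122). ANKRD26, which RUNX1 represses in megakaryocytes, rose from 1.37 to 6.58 CPM (2.27 ± 0.46, 0.0492), PMEPA1, a TGF-beta target, by 1.80 ± 0.32 (0.0280) and SC5D, of sterol synthesis, by 0.97 ± 0.18 (0.0359). PRF1, the perforin of cytotoxic cells, fell from 1.46 to 0.263 CPM (-2.46 ± 0.34, 0.00919).

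The genes that define the platelet lineage did not pass without block in CD41+ cells. The values here are of whole libraries and mix classes of cells. Within cluster 1 and cluster 2, GP9 and GP1BA were lower with the block only, as given below. Neither passed without block in the megakaryocyte-like class. Both arms were sorted by surface CD41 among CD34+CD38- cells, so the sort may hold ITGA2B, CD34 and CD38 alike within either gate. GP9 (-0.21 ± 0.33) and GP1BA (-0.14 ± 0.20), subunits of the receptor for von Willebrand factor, ITGA2B itself (0.04 ± 0.57; 428.8 against 416.9 CPM), TGFB1 (0.04 ± 0.38), CD38 (-0.05 ± 0.38) and PTPRC (0.00 ± 0.37) each had adjusted p = 1.0. PF4, a platelet chemokine, stood at 1225 ± 361 against 803.2 ± 169 CPM (0.61 ± 0.93, adjusted p = 1.0), CD34 at 0.33 ± 0.22 (0.877). With replicates 1 and 2 only, GP9 (-0.26, adjusted p = 7.21e-07), CD34 (0.24, 2.98e-05), TGFB1 (0.12, 0.00817) and PF4 (0.65, 0.0241) pass. Over all alternatives these adjusted p are the lowest of each gene, and 1.0 is the highest. MYH10, a non-muscle myosin that RUNX1 silences in megakaryocytes, stood at 0.64 ± 0.60 (adjusted p = 1.0) and passes with the block (0.71, adjusted p = 0.00800; adjusted p over all alternatives 5.8e-13 to 1.0).

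**Figure D2:**
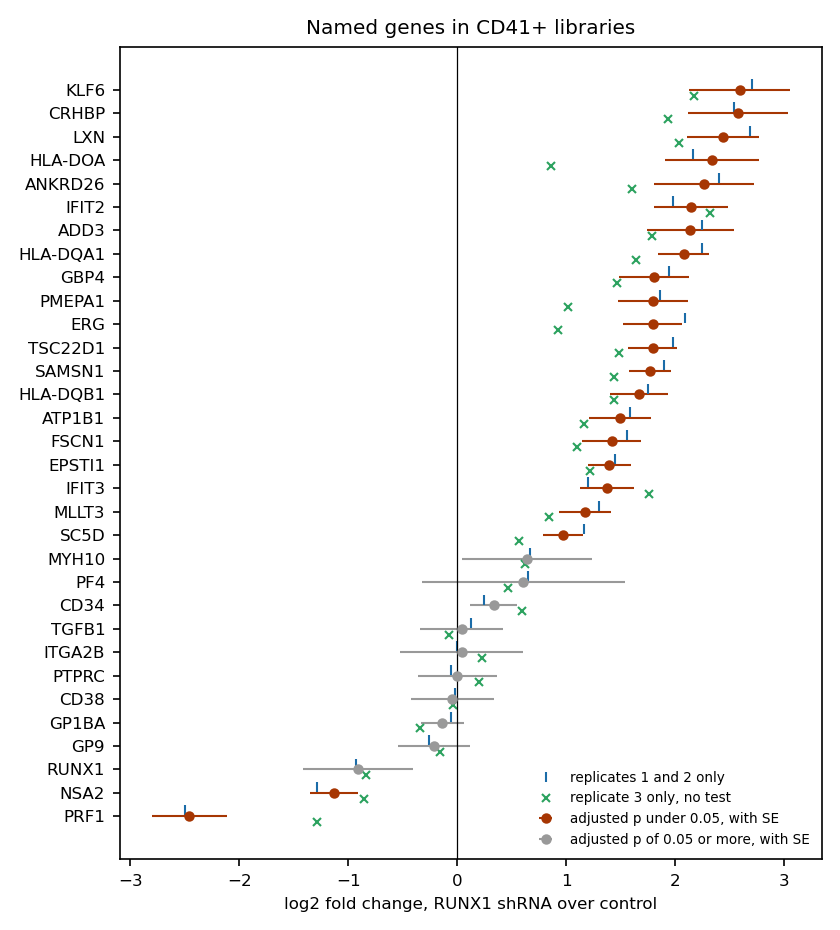
Log2 fold change of RUNX1 shRNA over control (horizontal axis) for the named genes (vertical axis) in CD41+ libraries, with bars of 1 SE from the fit without block, 3 libraries per group. KLF6 lies at 2.59, LXN at 2.44 and NSA2 at -1.13, and the platelet genes GP9 and GP1BA lie near 0 at -0.21 and -0.14. These are whole-library values, and within cluster 1 and cluster 2 GP9 and GP1BA were lower with the block only.

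The block fit calls 1639 genes higher and 658 lower, all 127 above among them; replicates 1 and 2 alone give 3924 and 3071, and DESeq2 246 and 52. Of genes called in replicates 1 and 2, 5503 of 6954 (79.1%) have the same sign in replicate 3. The 127 depend on single libraries. They become 4 without control CD41+ replicate 1 or control CD41+ replicate 2, 26 and 24 without RUNX1 shRNA CD41+ replicates 1 and 2, and 76 without control CD41+ replicate 3. Libraries outside the comparison count too, because the spread is estimated over all 12: the number is 460 without control CD41- replicate 3, 80 without control CD41- replicate 2, and 52 and 47 without RUNX1 shRNA CD41- replicates 1 and 2.

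Among the 35 gene lists, 13 differ from other genes in CD41+ cells by camera (10 higher, 3 lower), and 6 of them also with an estimated correlation; fry calls 13 too, camera with the block 15, and camera with block and estimated correlation 0. The 6 are MHC class II (camera adjusted p = 2.02e-16; adjusted p = 0.0210 with an estimated correlation), MYC and ribosome biogenesis (lower; median -0.49, 0 of 28 genes passing, 17 lower with the block; 3.24e-09; adjusted p = 0.0210 with an estimated correlation), complement and coagulation factors (median 0.39, 0 of 16; adjusted p = 0.0278 with an estimated correlation), endothelial markers (0.59, 1 of 8 higher; adjusted p = 0.0362 with an estimated correlation), TNF and NF-kB response (0.29, 0 of 32, 11 higher and 3 lower with the block; adjusted p = 0.0492 with an estimated correlation) and stem and multipotent progenitor markers (0.55, 2 of 16 higher; adjusted p = 0.0492 with an estimated correlation). Called by camera only were the genes RUNX1 represses in platelets (ANKRD26 and 1 other, median 1.45; adjusted p = 0.207 with an estimated correlation), p53 targets (0.24, 0 of 25; adjusted p = 0.0820 with an estimated correlation), interferon response (0.33; adjusted p = 0.0909 with an estimated correlation), immediate early genes (0.24, 1 of 27 higher; adjusted p = 0.207 with an estimated correlation), PI3K-AKT-mTOR and cytokine receptors (0.26, 0 of 33, 11 higher and 1 lower with the block; adjusted p = 0.503 with an estimated correlation), and, lower, nuclear oxidative phosphorylation (-0.15, 0 of 59; adjusted p = 0.833 with an estimated correlation) and T and NK markers (1 of 11 lower, adjusted p = 0.360 with an estimated correlation), where the median is 0.11 (0.16 with genes at 0 set at their bound) while the mean of -0.39 and the test point down.

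The other 22 lists did not differ. Medians of those tied to megakaryocytes were 0.22 in the platelet genes RUNX1 activates (0 of 16), 0.24 in megakaryocyte transcription factors (1 of 20 higher, ERG) and 0.20 in megakaryocyte markers (0 of 20). Those of growth were -0.05 in S phase (0 of 43), 0.03 in G2/M (0 of 54), -0.12 in DNA damage response (0 of 35), 0.16 in apoptosis regulators (0 of 24), 0.00 in cytosolic ribosomal proteins (0 of 84), -0.11 in mitochondrially encoded genes (0 of 13) and 0.01 in cholesterol synthesis (1 of 23 higher). Those of stress and signalling were 0.17 in TGF-beta signalling (1 of 33 higher, 11 higher and 2 lower with the block), -0.14 in heat shock (0 of 16), 0.00 in the unfolded protein response (0 of 24), -0.01 in hypoxia and glycolysis (0 of 29), 0.12 in MHC class I (0 of 12) and 0.31 in adhesion and homing (0 of 24). Markers of other lineages lay at 0.23 (erythroid, 0 of 18), 0.28 (basophil, mast cell and eosinophil, 0 of 13), 0.40 (granulocyte and monocyte progenitor, 0 of 14), 0.69 (monocyte and dendritic, 0 of 15), 0.09 (lymphoid progenitor and B, 0 of 10) and 0.60 (stromal, 0 of 3). With the block camera also calls megakaryocyte transcription factors and TGF-beta signalling.

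**Figure D3:**
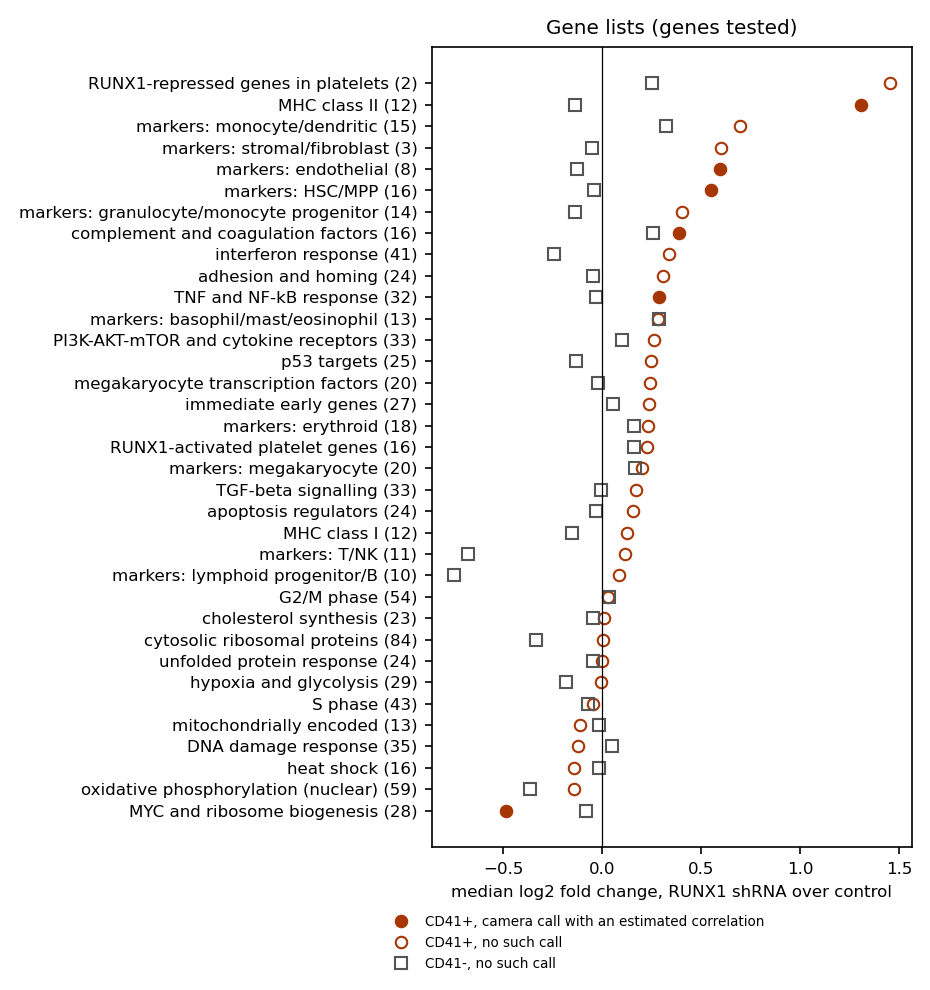
Median log2 fold change of RUNX1 shRNA over control (horizontal axis) of each gene list (vertical axis, genes tested in brackets) in CD41- and CD41+ libraries, 3 per group; points are medians and carry no error bars. MHC class II lies furthest to the right among lists of 10 or more genes in CD41+ cells, at 1.31, and at -0.14 in CD41- cells.

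What differs under the shRNA in CD41- cells, which hold the stem and multipotent progenitors? No gene passed (0 of 15726 by edgeR, 0 by DESeq2), with 122 at an unadjusted p under 0.05. With the block KLF6 alone passes, higher. Replicates 1 and 2 alone give 337 higher and 173 lower genes, of which 236 of 510 (46.3%) have the same sign in replicate 3. None of the genes looked up in advance passed without block: GP9 (-0.22 ± 0.37), TGFB1 (-0.26 ± 0.39), CD34 (-0.12 ± 0.22), CD38 (-0.03 ± 0.36), PF4 (0.01 ± 1.06), GP1BA (0.17 ± 0.25), PTPRC (0.22 ± 0.37), MYH10 (0.27 ± 0.60) and ITGA2B (0.40 ± 0.57), each with adjusted p = 1.0. With replicates 1 and 2 only, ITGA2B (0.43, adjusted p = 7.33e-10) and MYH10 (0.20, 0.0255) pass. Over all alternatives these are the lowest adjusted p of each, and 1.0 is the highest. Camera calls 11 lists, none of which holds with an estimated correlation (adjusted p = 0.159 to 0.821) or by fry. Higher were basophil, mast cell and eosinophil markers (median 0.29), complement and coagulation (0.26), and erythroid, megakaryocyte and RUNX1-activated platelet genes (0.16 each); lower were lymphoid (-0.75), T and NK (-0.68; -0.57 with genes at their bound) and interferon genes (-0.25). With the block camera loses T and NK markers and gains hypoxia and glycolysis (lower) and PI3K-AKT-mTOR and cytokine receptors (higher). With block and estimated correlation it calls 0. These medians do not carry over between replicates: that of erythroid markers was 0.62 in replicates 1 and 2 and -0.88 in replicate 3, that of cytosolic ribosomal proteins 0.06 and -0.77 (-0.33 over all libraries), that of oxidative phosphorylation genes 0.04 and -0.79 (-0.36) and that of monocyte and dendritic markers 0.41 and -0.63 (0.32). The number of lists called is 4 without control CD41- replicate 1, 3 without RUNX1 shRNA CD41- replicate 1, 5 without control CD41- replicate 2, 7 without RUNX1 shRNA CD41- replicate 2, and 17 with replicates 1 and 2 only.

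Is the effect of the shRNA different between the gates? No gene passed the test of the difference (0 by edgeR, 630 at an unadjusted p under 0.05; DESeq2 36 higher and 3 lower), so for the genes that rose in CD41+ cells a difference from CD41- cells is not shown without block. SAMSN1 (difference 1.92, adjusted p = 0.0723) and HLA-DQA1 (2.11, adjusted p = 0.0957) came closest among those named. With the block all 20 genes named as higher in CD41+ cells pass (adjusted p = 7.9e-05 to 0.0436). The block fit gives 349 higher and 42 lower, and replicates 1 and 2 give 2442 and 1855, of which 61.2% have the same sign in replicate 3. Without control CD41- replicate 3 the count is 14. Camera calls 11 lists (fry 7), 6 of them also with an estimated correlation: MHC class II (median difference 1.38; adjusted p = 0.0201 with an estimated correlation), interferon response (0.51; adjusted p = 0.0201 with an estimated correlation), TNF and NF-kB (0.35; adjusted p = 0.0266 with an estimated correlation), stem and multipotent progenitor markers (0.46; adjusted p = 0.0283 with an estimated correlation), endothelial markers (0.38; adjusted p = 0.0301 with an estimated correlation), all higher in CD41+ cells, and MYC and ribosome biogenesis (-0.35; adjusted p = 0.0266 with an estimated correlation). With the block camera also calls megakaryocyte transcription factors, TGF-beta signalling and immediate early genes (higher) and heat shock (lower). Camera with block and estimated correlation calls 0.

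What sets CD41+ apart from CD41- cells when RUNX1 is intact? CD41 is the sorting marker, so a higher ITGA2B (ENSG00000005961, chr17:44372180-44389505, minus) follows from the sort: 416.9 ± 182 against 35.8 ± 16.8 CPM (log2 fold change 3.54 ± 0.63, adjusted p = 0.00147). In control libraries 1624 genes were higher and 2549 lower in CD41+ cells. All 20 megakaryocyte markers were higher, with a median of 5.66. PPBP (9.52 ± 0.98, adjusted p = 3.34e-05) and PF4 (ENSG00000163737, chr4:73981077-73982124, minus; 9.30 ± 1.35, 0.000384), platelet chemokines, went from about 1 CPM or less to 305.3 and 803.2. With 1 library omitted the log2 fold change of PF4 ran from 8.71 to 13.2. GP1BA (6.61 ± 0.26, 9.3e-08), GP9 (6.18 ± 0.41, 2.42e-06), the collagen receptor GP6 (6.64 ± 0.36, 8.21e-07), platelet tubulin TUBB1 (6.65 ± 0.34, 5.74e-07), factor XIII subunit F13A1 (6.16 ± 0.50, 6.13e-06) and LTBP1, which binds latent TGF-beta (8.03 ± 0.79, 2.54e-05), rose along with TGFB1 (1.91 ± 0.40, 0.00391) and thrombospondin THBS1 (5.23 ± 0.58, 5.65e-05). Globins HBD (4.66 ± 0.47, 2.9e-05), HBG1 and HBG2 were higher too, as were the chemokine CXCL8 (2.99 ± 0.25, 7.4e-06), VEGFA (2.83 ± 0.43, 0.000506) and the cell cycle inhibitor CDKN1A (2.77 ± 0.25, 1.14e-05).

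CD41+ control cells had little of the genes of stem and myeloid progenitors. AVP (ENSG00000101200, chr20:3082556-3084724, minus), the most specific transcript of human stem cells, was at 1.28 against 373.4 CPM (-8.10 ± 0.67, adjusted p = 7.22e-06), SPINK2 at 2.77 against 604.3 (-7.88 ± 0.68, 9.81e-06), the cytokine receptor FLT3 at -6.99 ± 0.40 (9.93e-07), the myeloid factor CEBPA at -6.44 ± 0.43 (2.42e-06) and S100A9 at -8.18 ± 0.77 (1.8e-05). S100A8 and IRF8 had no UMI in the 3 control CD41+ libraries and 5.22 and 3.39 CPM in CD41-. GLIPR1 (-6.61 ± 0.27, 1.05e-07), HLA-DQA1 (-3.70 ± 0.25, 2.19e-06), ERG (-3.57 ± 0.28, 5.19e-06), CD34 (-1.82 ± 0.22, 0.000111) and CD38 (-1.58 ± 0.38, 0.00874) were lower. RUNX1 was at 0.78 ± 0.51 (adjusted p = 0.308) and passes with the block (0.81, adjusted p = 1.81e-05; adjusted p over all alternatives 3.44e-20 to 0.590). By list, 11 of 12 MHC class II genes, 11 of 16 stem and progenitor markers and 12 of 15 monocyte and dendritic markers (median -4.58, -4.45 with genes at their bound) were lower, and 25 of 54 G2/M genes, 11 of 16 coagulation factors and 10 of 16 RUNX1-activated platelet genes were higher. Camera calls 16 lists; 6 hold with an estimated correlation (megakaryocyte markers, adjusted p = 0.00157 with an estimated correlation, coagulation, stem and progenitor markers, RUNX1-activated platelet genes, MHC class II and G2/M). With the block camera loses adhesion and homing (lower). With block and estimated correlation it calls 0. The block fit calls 3884 higher and 4999 lower genes, and replicates 1 and 2 call 5510 and 5943.

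Does the gate look the same under the RUNX1 shRNA? Largely, by the genes that pass: 1781 were higher and 1938 lower in CD41+ than in CD41- cells, and the gates of both arms share 1302 higher genes (184 under independence) and 1722 lower ones (314). PF4 (9.89 ± 1.41, adjusted p = 0.000406), PPBP (8.50 ± 0.95, 7.8e-05), GP1BA (6.30 ± 0.28, 2.98e-07), GP9 (6.18 ± 0.43, 3.99e-06), ITGA2B (3.19 ± 0.62, 0.00293) and F13A1 (6.51 ± 0.53, 8.6e-06) were higher, and all 20 megakaryocyte markers rose again (median 5.62). AVP (-7.15 ± 0.63, 1.44e-05), SPINK2 (-6.88 ± 0.64, 2.08e-05), FLT3 (-6.52 ± 0.38, 1.77e-06) and CD34 (-1.37 ± 0.22, 0.000834) were lower, as was CD38 (-1.60 ± 0.38, 0.00920), whose libraries overlap. ERG was lower by a smaller step than in control (-1.87 ± 0.26, 0.000301), with a difference between the arms that does not pass without block (1.70, adjusted p = 0.295) and passes with it (1.86, adjusted p = 0.000303). MYH10 (0.33 ± 0.60, adjusted p = 0.766) and PTPRC (-0.55 ± 0.37, 0.340) pass only with the block (0.43, adjusted p = 0.0432, and -0.52, adjusted p = 0.00939) or in replicates 1 and 2. Their adjusted p over all alternatives ran from 3.51e-05 to 0.988 and from 1.61e-15 to 0.590. CXCL8 (4.04 ± 0.27, 3.01e-06), CXCL3 (4.59 ± 0.40, 1.35e-05) and CCL5 (3.81 ± 0.33, 1.2e-05), inflammatory chemokines, were higher. MHC class II genes were lower in 8 of 12 (median -1.62), a camera call lost with an estimated correlation (adjusted p = 0.0592 with an estimated correlation). Camera calls 17 lists and 6 hold: megakaryocyte markers (adjusted p = 8.38e-06 with an estimated correlation), RUNX1-activated platelet genes, coagulation, stem and progenitor markers, and G2/M and granulocyte and monocyte progenitor genes (adjusted p = 0.0457 with an estimated correlation for each). With the block camera loses basophil, mast cell and eosinophil markers (lower) and gains megakaryocyte transcription factors (higher), MYC and ribosome biogenesis and T and NK markers (lower). With block and estimated correlation it calls 0. The block fit calls 4133 higher and 4326 lower, replicates 1 and 2 call 5544 and 5750, and the count is 5609 without control CD41- replicate 3.

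Which cells make up the fractions? The 13 clusters give 12 classes. The larger classes of CD41- cells were stem and multipotent progenitor-like (AVP, SPINK2, HOPX), cluster 3 (AVP, BEX1 and the mitotic TOP2A; 20.8% under the shRNA and 16.9% in control), cluster 6 (4.41% and 27.7%), erythroid-like (KLF1, TFRC) and granulocyte and monocyte progenitor-like (MPO, CTSG, CEBPA). CD41+ cells fell into cluster 1 (HBD, ITGA2B, GP1BB), cluster 2 (the mitotic genes UBE2C, CENPE, PLK1) and a megakaryocyte-like class (PPBP, PF4, TUBB1, VWF, SELP). The megakaryocyte-like share of CD41+ cells was 22.3%, 25.3% and 17.1% under the RUNX1 shRNA (mean 21.5%, SD 4.16) and 12.6%, 12.6% and 11.3% in control (12.2%, SD 0.754). The log2 fold change of 0.82 ± 0.73 does not pass (edgeR adjusted p = 0.905; exact permutation p = 0.1, the smallest possible with 3 against 3), with the block neither (0.82, adjusted p = 0.925); in replicates 1 and 2 it does (0.91, adjusted p = 2.28e-15; adjusted p over all alternatives 2.28e-15 to 0.985). The p-value of replicates 1 and 2 rests on the small spread between them, 12.6% each in control, which may be technical. That holds for the erythroid-like p-value of replicates 1 and 2 below as well. Cluster 1 stood at 43.9% (SD 3.45) against 49.5% (SD 3.15), and cluster 2 at 26.4% (SD 3.83) against 29.5% (SD 0.737). In CD41- cells the erythroid-like share was 13.8% (SD 8.02) against 8.47% (SD 6.30), or 14.2% against 10.1% with the cells of cluster 6 left out (adjusted p = 0.810; in replicates 1 and 2 0.60, adjusted p = 1.97e-10; adjusted p over all alternatives 1.97e-10 to 0.990). Stem and multipotent progenitor-like cells were 45.8% (SD 5.29) against 34.2% (SD 21.5), or 48.1% against 46.8% with the cells of cluster 6 left out, and lower under the shRNA in replicates 1 and 2 (log2 -0.12). Granulocyte and monocyte progenitor-like cells were 6.17% (SD 0.254) against 5.28% (SD 3.23), a direction that turns in replicates 1 and 2 (log2 -0.18) and with cluster 6 left out (-0.19). The control mean is pulled by replicate 3, in which 79.4% of cells (95% interval 78.3% to 80.4%) fell into cluster 6, against 1.88% and 1.72% in the other control libraries. No class passed without block in either gate.

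**Figure D4:**
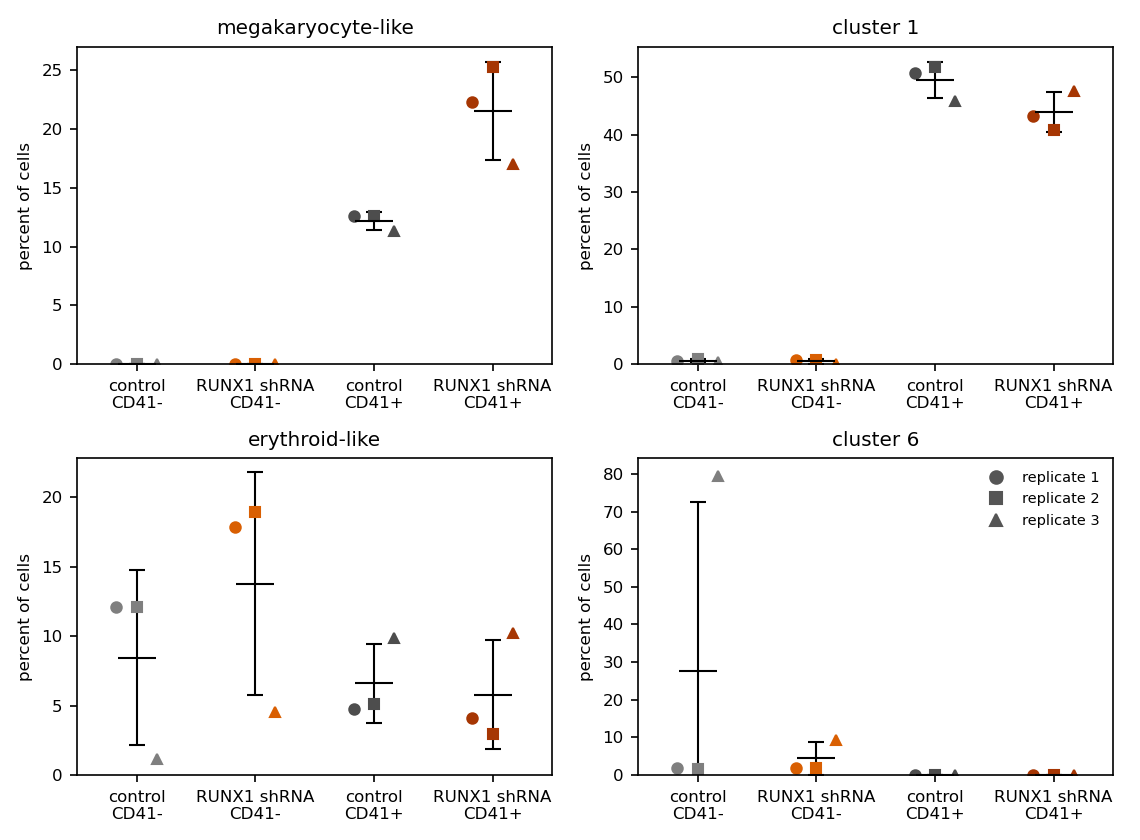
Percent of cells in a class (vertical axis) by group (horizontal axis), control and RUNX1 shRNA in CD41- and CD41+ libraries. Panels show selected classes, with the megakaryocyte-like and erythroid-like classes among them. Marks with lines are means of 3 libraries with SD, limited at 0 where the SD exceeds the mean, and points are libraries. The megakaryocyte-like class of CD41+ libraries lies at 12.2% in control and 21.5% under the RUNX1 shRNA.

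Within which cells do the CD41+ changes occur? The megakaryocyte-like class showed the most: 464 genes rose and 251 fell (3013 RUNX1 shRNA and 2923 control cells). ALKAL2, a receptor tyrosine kinase ligand (3.56 ± 0.22, adjusted p = 0.000404), ARID5B, a chromatin factor (3.58 ± 0.25, 0.000404), LXN (3.09 ± 0.22, 0.000404), GBP4 (3.07 ± 0.21, 0.000404) and the caveolar CAV2 (2.81 ± 0.20, 0.000404) rose. KAZN, of the cell cortex (-2.82 ± 0.22, 0.000585), NSA2 (-1.68 ± 0.18, 0.00205), the nucleolar GPATCH4 (-1.98 ± 0.25, 0.00469), the nuclear receptor NR2F6 (-1.50 ± 0.19, 0.00469) and the disulphide isomerase PDIA5 (-1.86 ± 0.25, 0.00638) fell. Of 28 MYC and ribosome biogenesis genes 14 fell (23 over the list alone, median -1.06), 6 of 7 MHC class II genes rose, 7 of 31 interferon and 6 of 28 TGF-beta genes rose, and 4 of 43 S phase and 5 of 50 G2/M genes fell (35 and 36 with the block). None of the 20 megakaryocyte markers passed (13 higher with the block), nor did GP1BA (-0.04), GP9 (-0.18) or ITGA2B (0.08). Of 15 platelet genes RUNX1 activates, 2 fell in this class (8 higher and 3 lower with the block). They are ITGA2 and MYL9, named after their values were seen. RUNX1 itself was at -0.69 (adjusted p = 0.284; block -0.65, adjusted p = 2.41e-08). The block fit calls 2275 higher and 2263 lower genes, DESeq2 552 in all; the 715 above become 34 and 30 without control CD41+ replicates 1 and 2, 90 and 89 without RUNX1 shRNA CD41+ replicates 1 and 2, 1115 without control CD41+ replicate 3 and 2594 without RUNX1 shRNA CD41+ replicate 3.

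Other CD41+ classes changed in fewer genes. In cluster 1, 84 genes rose and 8 fell (block 2167 and 1549): HLA-DQA1 (2.65 ± 0.22, adjusted p = 0.000534), LXN (2.43 ± 0.23, 0.000925), BST2, an interferon-induced tether (2.71 ± 0.26, 0.000925), TM4SF1 (4.32 ± 0.47, 0.00244) and HLA-DRA (1.63 ± 0.19, 0.00441) rose, and the collagen receptor subunit ITGA2 (-2.35 ± 0.30, 0.00734), SH3BP5 (-2.25 ± 0.33, 0.00745) and PDE5A, a phosphodiesterase of platelets (-1.71 ± 0.30, 0.0252), fell. MHC class II genes rose in 7 of 11 (all 11 over the list alone). Of the platelet genes RUNX1 activates, 1 of 15 fell in cluster 1 and in cluster 2, ITGA2 in each case, which for cluster 2 was also looked up after the values were seen (5 higher and 5 lower with the block in either). GP9 (-0.61 and -0.36) and GP1BA (-0.53 and -0.29) are lower in clusters 1 and 2 with the block only. In cluster 2, 100 rose and 24 fell (block 1908 and 1590), with LXN (2.58), BST2 (2.14), TSC22D1 (1.83) and HOXB2 (2.20) up and SH3BP5 (-2.08), NR2F6 (-1.42), NSA2 (-1.13) and CSF1 (-1.83) down. Of phase genes there, 1 of 54 G2/M genes rose and 0 of 43 S phase genes passed (medians 0.23 and 0.06; with the block 32 and 15 higher, 1 and 3 lower). In cluster 1 none of 53 G2/M genes passed (4 higher and 27 lower with the block). Differences between classes were not tested. In erythroid-like CD41+ cells 2 genes rose, LXN (2.12) and TSC22D1 (1.27). In erythroid-like CD41- cells KLF6 rose (2.59 ± 0.36, adjusted p = 0.0161). No gene passed in stem and multipotent progenitor-like, cluster 3 or granulocyte and monocyte progenitor-like CD41- cells (64, 57 and 46 at an unadjusted p under 0.05; DESeq2 0 in each; block 63, 45 and 8).

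These class counts also rest on few libraries. In cluster 1 the 92 become 5 and 3 without control CD41+ replicates 1 and 2, 6 without RUNX1 shRNA CD41+ replicate 1 or replicate 2, 154 without control CD41+ replicate 3 and 330 without RUNX1 shRNA CD41+ replicate 3. In cluster 2 the 124 become 29, 15, 32 and 39 without those 4 libraries of replicates 1 and 2, 270 without control CD41+ replicate 3 and 402 without RUNX1 shRNA CD41+ replicate 3. For erythroid-like CD41+ cells the count is 9 without control CD41- replicate 3, 7 without control CD41+ replicate 3, 12 without RUNX1 shRNA CD41+ replicate 3 and 1 without any other. For erythroid-like CD41- cells it is 2 without RUNX1 shRNA CD41+ replicate 3 and 0 without control CD41- replicates 1 or 2, control CD41+ replicate 2 or any RUNX1 shRNA CD41- library. Without control CD41- replicate 3 the counts of 0 become 8 in stem and multipotent progenitor-like cells, 9 in cluster 3 and 8 in granulocyte and monocyte progenitor-like cells.

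Do the scored cell cycle phases differ? Phase scores put 87.4% (SD 3.44) of RUNX1 shRNA and 96.0% (SD 2.16) of control CD41+ cells in S or G2/M, 8.58 percentage points lower (exact permutation p = 0.1, the smallest possible; sign-flip p = 0.25, the smallest possible). G2/M alone was 46.2% against 62.1% and S 41.2% against 33.9%. Unthinned counts give 73.8% against 87.5% in S or G2/M, and thinning to 1500 UMIs 68.4% against 82.6%. The direction of S alone turns there, to 26.4% against 28.7% unthinned and 23.5% against 27.1% at 1500 UMIs. In CD41- cells the difference was 12.4 points in the other direction and -2.71 unthinned. The 12.4 rests on replicate 3 (42.1 points; -2.51 in replicates 1 and 2), where only 34 RUNX1 shRNA cells had 3000 UMIs. Free RNA in droplets can also carry these genes, and thinning to 3000 UMIs left out 14408 control and 4046 RUNX1 shRNA CD41+ cells; the scores measure transcripts and not division.

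How do the authors' own tables compare? For 5 of the 7 CD41+ clusters in them, 89.7% to 97.0% of listed genes have the same sign here; 2 others, with 0 and 1 genes past 0.05 in the authors' values, have 56.8% and 66.9%. In the 6 CD41- clusters, of 5 to 30 genes each, it is 55.6% to 100%. Their clusters 1, 5, 6 and 7 have 10 of 10, 15 of 18, 17 of 18 and 22 of 30 genes. With replicates 1 and 2 only these become 5, 7, 15 and 5. Cluster 8 goes from 10 to 18 of 18, and cluster 3 stays at 5 of 5. The named populations carry no gate in the table, so MkPs_1 and MkPs_2 were set against CD41+ libraries and the others against CD41- libraries by their names alone. For MkPs_1 and MkPs_2 the share is 96.5% and 95.4%. For the gate it is 83.6% in control and 84.6% under the shRNA. In the other populations it ranges from 19% (HSCs, 4 of 21 genes) and 39.8% (MEPs, 45 of 113) to 87.5% (LMPPs). With replicates 1 and 2 only, HSCs have 17 of 21 and MEPs 94 of 113, while LMPPs have 41 of 128 and the lympho-myeloid population 92 of 186 (160 with all libraries). LXN and KLF6 are listed higher in the authors' CD41+ cluster 1, by 1.33 and 0.95 in log2. PF4 is listed lower there (-0.41 in log2; deposited adjusted p = 9.11e-09) and in MkPs_1 (ratio 0.552; 4.6e-08) but higher in MkPs_2 (ratio 1.43; 0.000203). GP9 is lower in MkPs_1 (ratio 0.424; 0.000668). The fit without block calls neither gene in CD41+ libraries. These tables come from the same cells, so equal signs are no independent test.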

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

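Chosen after the results were seen were the tests on added spread in replicate 3 and on a deeper loss of RUNX1; the test on class composition was written before. What drew attention is a difference between groups: with the replicate number as a block, 349 genes had a higher RUNX1 shRNA effect in CD41+ than in CD41- libraries and 42 a lower one, while the fit without block called 0.

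The 20 genes named as higher in CD41+ cells are called in this test; they were chosen for that rise, so their direction is no separate evidence. The differences of log2 fold changes, CD41+ minus CD41-, are 2.19 for LXN, 2.26 for ANKRD26, 2.26 for CRHBP, 2.19 for HLA-DOA, 2.10 for HLA-DQA1 and 1.76 for HLA-DQB1. Interferon-induced genes show 2.14 (IFIT2), 1.82 (IFIT3), 1.39 (EPSTI1) and 1.60 (GBP4). ADD3 is at 2.0, SAMSN1 at 1.91, ERG at 1.86, FSCN1 at 1.62, TSC22D1 at 1.57, PMEPA1 at 1.49, ATP1B1 at 1.26, MLLT3 at 0.95 and SC5D at 0.90. KLF6 has 1.1 and is the only one of them that also passes with the block in CD41- libraries.

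The first pattern to weigh is that the shRNA changes more genes in CD41+ than in CD41- cells. Spread added by the replicate 3 libraries is excluded as the sole cause: with replicates 1 and 2 only, 510 genes pass in CD41- and 6995 in CD41+. A shift between the clusters as made here is excluded as the sole cause of the median change of 106 of the 127 genes called. These are the genes measured in cluster 1, where their median change is 0.952 of that in whole libraries (1.71 against 1.80 in log2). Of the 106, 57 are also called in cluster 1, so single genes are not settled. Cluster 1 holds a large part of the same CD41+ cells. All 127 genes also pass with the block, so none of them helped to define the clusters. A shift between cell states that they mark would stay inside cluster 1 and was not tested. Clustered on all variable genes, the megakaryocyte-like share of CD41+ cells is 41.5% under the shRNA against 17.8% in control. A deeper loss of the RUNX1 transcript in CD41+ cells cannot be told apart from a stronger response to the same loss. In whole libraries the difference of its log2 fold changes is -0.54 (SE 0.174, unadjusted p = 0.00662 from edgeR with the block). In erythroid-like cells, the only class measured in all libraries of both gates, the order of the losses depends on the fit. RUNX1 was at -0.71 in CD41+ against -0.83 in CD41- with the block, and at -0.85 (SE 0.44) against -0.68 (SE 0.43) without. The difference within the class was not tested. The block fit calls 295 genes there against 35, and the fit without block 2 against 1. The class joins cluster 4 and the globin-rich cluster 12, so the gates may hold different erythroid-like cells. Megakaryocyte-like CD41+ cells had 4538 block calls at a RUNX1 change of -0.65 with the block. Erythroid-like CD41- cells had 35 at -0.83. Such classes differ in more than the gate, so this comparison does not separate the explanations either. That the hairpin may act more strongly where RUNX1 is more highly expressed, or that CD41+ cells may depend more on its dose, remain hypotheses that these values cannot separate.

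Other ways to split the libraries into groups test whether such counts arise by grouping alone. In CD41+ libraries the real split gives 127 genes and the highest other split 0, so 1 of 10 splits has a count as large. Where the real count is 0 every split is as large by definition and nothing is tested: this holds for CD41- libraries (10 of 10, highest other 0) and for the difference between gates (30 of 30, highest other 3). With 3 against 3 libraries the splits are too few for a share under 0.05.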

How the results depend on the processing

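Chosen after the results were seen were the settings of replicates 1 and 2 only, both CD41- replicate 3 libraries left out, cluster 6 barcodes left out and clustering on all variable genes. Of 222 named results that pass, 5011 of 5283 values under the alternatives kept direction and side of the threshold, 272 became weaker and 0 reversed. Most of these results are of the gate. Each named shRNA result that passes in CD41+ cells loses its call under at least 1 alternative. Their highest adjusted p over the alternatives ran from 0.0623 (SAMSN1) to 0.975 (ANKRD26), with 0.107 for LXN and 0.196 for KLF6. Of 24 named results that do not pass, 489 of 576 values stayed, 17 became stronger and 70 reversed. For all changes below the cause was not tested, except that thinning to the smallest total leaves 1.40 M UMIs per library and that omissions leave fewer libraries.

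The replicate block moved every gene count: 1 in CD41-, 2297 in CD41+, 8883 and 8459 for the gate in control and under the shRNA, and 391 for the difference. It changed no call of a list or of a gene named in whole libraries other than those given beside the results. Replicates 1 and 2 only gave 510, 6995, 11453, 11294 and 4297. In CD41+ cells the count of 127 became 298 with DESeq2, 57 with the stricter cell filter, 5 with thinned libraries, 684 with both CD41- replicate 3 libraries left out and 303 without cluster 6. The gate in control became 2513 with only the libraries compared and 1387 with thinned libraries. The gate under the shRNA became 1354 with thinned libraries and 5923 with both CD41- replicate 3 libraries left out. The difference became 39 with DESeq2, 33 with both CD41- replicate 3 libraries left out and 19 without cluster 6. Omitting 1 library gave 0 to 0, 4 to 460, 2844 to 5286, 2492 to 5609 and 0 to 14.

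Lists called in CD41- cells became 0 with an estimated correlation, 0 with fry and 17 with replicates 1 and 2. They became 6 with an estimated correlation in CD41+ cells and in the gate of either arm, and 26 with fry in the gate under the shRNA. Omitting 1 library gave 3 to 14, 10 to 15, 14 to 17 and 16 to 22.

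RUNX1 became stronger with the block (-0.90) and with replicates 1 and 2 (-0.93) in CD41+ and with replicates 1 and 2 (-0.42) in CD41- cells. Omitting 1 library gave -1.22 to -0.62 and -0.69 to -0.07. For the gate under the shRNA (0.22, adjusted p = 0.819) it became stronger with replicates 1 and 2 (0.23, adjusted p = 2.49e-05; over all alternatives 2.49e-05 to 0.993). It reversed to -0.0698 with both CD41- replicate 3 libraries left out, and omitting 1 library gave -0.0668 to 0.52.

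Reversed in CD41- cells: CD34 (0.0196 thinned, 0.0303 replicates 1 and 2, 0.0301 CD41- replicate 3 out), CD38 (0.0159 DESeq2, 0.00718 block, 0.0861 strict filter, 0.0592 thinned, 0.0392 replicates 1 and 2, 0.0344 CD41- replicate 3 out), GP1BA (-0.58 thinned), GP9 (0.10 block, 0.32 replicates 1 and 2, 0.32 CD41- replicate 3 out), PF4 (-0.195 DESeq2, -0.0399 only the libraries compared, -1.79 thinned) and TGFB1 (0.0887 replicates 1 and 2, 0.0886 CD41- replicate 3 out). Omitting 1 library gave CD38 -0.276 to 0.228, GP1BA -0.00982 to 0.287, GP9 -0.437 to 0.256, MYH10 -0.101 to 0.617, PF4 -0.679 to 3.92, PTPRC -0.101 to 0.424 and TGFB1 -0.488 to 0.306.

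Reversed in CD41+ cells: CD38 (0.0314 block, 0.263 strict filter), GP1BA (0.0914 thinned), ITGA2B (-0.0113 strict filter, -0.00327 replicates 1 and 2), PTPRC (-0.0369 DESeq2, -0.0377 RLE, -0.0298 no count filter, -0.0406 only the libraries compared, -0.0253 strict filter, -0.0600 replicates 1 and 2, -0.00416 CD41- replicate 3 out) and TGFB1 (-0.0106 DESeq2, -0.0114 RLE, -0.0109 only the libraries compared). With 1 library omitted CD38 ran from -0.215 to 0.0726, ITGA2B from -0.283 to 0.323, PTPRC from -0.223 to 0.167 and TGFB1 from -0.140 to 0.310. For the gate MYH10 reversed in control (0.00216 RLE, 0.16 thinned; -0.444 to 0.234 with 1 library omitted) and under the shRNA (-0.0233 CD41- replicate 3 out; -0.0214 to 0.629 with 1 library omitted). None of these passes the threshold.

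Shares: the megakaryocyte-like change became stronger with replicates 1 and 2 (0.91) and ranged from 0.69 to 0.97 with 1 library omitted. The erythroid-like change became stronger in CD41- (0.60, replicates 1 and 2; 0.21 to 1.12 with 1 library omitted) and in CD41+ became stronger with replicates 1 and 2 (-0.47), reversed when clustered on all variable genes (0.60) and ranged from -0.89 to 0.22. The stem and multipotent progenitor-like change reversed with replicates 1 and 2 (-0.12; -0.0256 to 0.72 with 1 library omitted), and the granulocyte and monocyte progenitor-like change with replicates 1 and 2 (-0.18) and without cluster 6 (-0.19), with -0.208 to 0.52 when 1 library was omitted. Phase shares in CD41- reversed without thinning (-2.71) and ranged from -0.53 to 19.2; in CD41+ they ranged from -10.3 to -6.87.

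Within classes the block gave 63 (stem and multipotent progenitor-like), 3716 (cluster 1), 3498 (cluster 2), 45 (cluster 3), 35 (erythroid-like CD41-), 295 (erythroid-like CD41+), 8 (granulocyte and monocyte progenitor-like) and 4538 (megakaryocyte-like); replicates 1 and 2 gave 82, 4502, 4127, 43, 97, 497, 9 and 5036. DESeq2 gave 148 in cluster 1, 199 in cluster 2 and 14 in erythroid-like CD41+ cells, and RLE 0 in erythroid-like CD41- cells. Omitting 1 library gave 0 to 8, 3 to 330, 15 to 402, 0 to 9, 0 to 2, 1 to 12, 0 to 8 and 30 to 2594.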

Other observations

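Chosen after the results were seen were the tests on shRNA-responsive genes in the clustering, on deeper cells, on free RNA and on a change shared by the replicate 3 libraries; the splits were planned before. HLA-DRA, the alpha chain of HLA-DR, was detected in more cells under the shRNA in the CD41+ gate; free RNA was not measured. At 1500 UMIs per cell it was seen in 44.1%, 42.2% and 40.6% of RUNX1 shRNA cells and in 22.2%, 21.5% and 22.4% of control cells, against 73.1% to 82.2% in CD41- libraries. At full depth the shares were 57.6% to 60.1% and 31.7% to 39.4%. With the block RUNX1 itself was lower in CD41+ cells of cluster 1 (-0.92), cluster 2 (-1.12), the erythroid-like class (-0.71) and the megakaryocyte-like class (-0.65). In CD41- cells it was lower in the erythroid-like (-0.83), cluster 3 (-0.37) and stem and multipotent progenitor-like (-0.33) classes. It did not pass in granulocyte and monocyte progenitor-like cells (-0.33, adjusted p = 0.999) or cluster 6 (-0.16, adjusted p = 1.0), and without block it passed in no class.

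The second pattern to weigh is the higher megakaryocyte-like share in RUNX1 shRNA CD41+ libraries. Deeper cells in those libraries are excluded as the sole cause of a higher share of cells with both PF4 and PPBP. With every cell thinned to 1500 UMIs, that share was still higher by 2.44 points on average (SD 0.432 over 3 replicate numbers). It was 12.4%, 13% and 9.55% against 9.74%, 10.2% and 7.6%. In CD41- libraries it reached 0.00931% at most. Those hold almost no megakaryocyte-like cells, so this value does not measure free RNA in CD41+ libraries, and thinning does not remove such RNA. The clusters were not remade on thinned counts, so the part of depth in the megakaryocyte-like share itself was not tested. PF4 alone does not follow, at 35.3%, 38.3% and 27.6% against 36.7%, 36.7% and 26.5%. Whether shRNA-responsive genes shape the clusters cannot be told apart from a true rise. Clustered without them, the lowest shRNA share lies 4.45 points above the highest control share, but the gap over 4 such clusterings runs from -4.98 to 4.82 and 2 of them overlap. Clustered with all variable genes the shares are 41.5% against 17.8%. A rise in mature megakaryocyte-like cells is thus a hypothesis.

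The third pattern to weigh is that 79.4% of control CD41- replicate 3 cells form cluster 6, which holds AVP, SPINK2 and HOPX but little mitochondrial RNA (median 1.45%) and little MALAT1 (748 CPM without TMM scaling). A change shared by the replicate 3 libraries cannot be told apart from one in this library alone: 9.34% (95% interval 7.43% to 11.5%) of RUNX1 shRNA CD41- replicate 3 cells fall there, far from 79.4% but above the 1.98% and 1.91% of replicates 1 and 2, and only 1 other CD41- library of replicate 3 exists. Barcodes that hold only free RNA cannot be told apart from cells. Those of the cluster had a median of 3625 UMIs, against 2241 to 4002.5 in the other clusters. The median ratio of variance to mean over genes is 1.02 in the cluster, near the 1 of pure sampling. It is 1.07 to 1.35 in 45 other sets of cells. Of those sets, 17 also met the bound set for free RNA, so the ratio alone does not separate free RNA from cells. Free RNA that has lost nuclei and mitochondria might look so, and so might damaged cells; no biological explanation was tested.

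For the other counts the real split and the highest other split were 4173 and 0 (gate in control), 3719 and 0 (gate under the shRNA), 92 and 0 (cluster 1), 124 and 0 (cluster 2), 715 and 0 (megakaryocyte-like), 1 and 0 (erythroid-like CD41-) and 2 and 0 (erythroid-like CD41+), each with 1 split of 10 as large. They were 0 and 0 in stem and multipotent progenitor-like, cluster 3 and granulocyte and monocyte progenitor-like cells, where 10 of 10 are as large by definition. For lists they were 11 and 12 in CD41- (2 of 10 as large), 13 and 8 in CD41+ (1), 16 and 16 for the gate in control (2) and 17 and 16 for the gate under the shRNA (1). Of the other splits of the CD41- libraries, 1 gives 12 lists and 8 give 3 to 6.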
